A study of Mus musculus with 8 samples.

How the data were processed

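The series compares back skin of mouse embryos at embryonic day 14.5 between 2 genotypes, GNAQ R183Q and wild type, with 4 libraries in each group. Skin was dissected in cold buffer and kept in Trizol, RNA was purified with Trizol and RNeasy columns, and stranded Illumina TruSeq libraries were made from total RNA, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels give all 8 libraries the same batch, and the sex and litter of the embryos were not given in the sources used here.

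The values used are a table of the authors' own comparison of the 2 genotypes with 20152 gene symbols, none duplicated, of which 4242 have predicted-model names. The submitters' processing notes name DESeq2 and the mouse genome build mm39, with no version of DESeq2. The aligner, the counter, the annotation, the strand setting, the filter on genes and the DESeq2 design are not given in the sources used here. Average expression is a signal that the authors averaged over libraries, per the file headers, and its values are read here as normalized counts because they are never negative, are not whole and sum to 2.68e+07. The log2 fold change is the authors' value for GNAQ R183Q over control, per the file headers, and it takes the sign of the mean z-score of the mutant group in all but 4.31% of genes and in every called gene. The p-value and adjusted p-value are the authors', per the file headers, and Benjamini-Hochberg adjustment of the p-values over all genes gave the deposited adjusted values back within rounding. The z-score columns are scores that the authors computed from log2 CPM across libraries, per the file headers, as a mean and a median per genotype. The largest absolute mean z-score was 0.924, under the limit of 0.935 that 4 against 4 libraries with a sample SD allow.

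Before the data were examined, a count test with edgeR was planned for a count table, and the authors' own adjusted p for a table without values per library. The latter applied. The threshold was an adjusted p of 0.05, and a second count took genes that also changed at least 2-fold. The depth per library is unknown, so no interval or floor that needs counts is given. A standard error was derived for each gene as the absolute log2 fold change divided by the normal quantile of the authors' p, which assumes a Wald test against the normal distribution, and the implied 95% interval spans 1.96 such errors on each side. The median implied error was 1.20 at an average expression of 1 to 10 and 0.140 in the 5627 genes of highest expression, so genes of low expression have wide intervals. Replicates count as separate samples because the submitters describe them as biologically independent.

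A linear model of log2 CPM with genotype as the only term was rebuilt from the mean z-scores, which fix the share of variance between genotypes, and gave a p with 6 residual degrees of freedom and no sharing of spread between genes. A mean z-score above 0.810 in size can be reached only if all 4 libraries of one genotype lie above all 4 of the other, and it served as the separation criterion. Transcript length and GC content were taken by gene symbol from the longest transcript, protein-coding ones first, of the GENCODE vM21 annotation of GRCm38, which is not the authors' build, so no coordinates are printed. Length and GC were matched for 88.7% of genes, 97.2% of those with a mean of at least 1 CPM and 96.9% of called genes. A trend of the log2 fold change on both, with natural splines fitted to 13955 genes of at least 1 CPM, was removed in an alternative. Which tested genes neighbour each other was taken from RefSeq genes of GRCm38.p6, with genes that were not tested left out of the order.

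Gene lists were fixed in advance: 49 lists with 851 different genes, of which 827 were in the table. Some genes sit in several lists, among them Klf4, Perp, Cdkn1a, Sesn2 and Notch3. Lists with at least 4 measured members, 48 in all, were tested by camera in limma 3.58.1, on the signed normal quantiles of the authors' p-values, with a preset correlation of 0.01, and Benjamini-Hochberg adjustment over the 48. A correlation could not be estimated from a table of means, so preset values of 0.05 and 0.1 were tried instead. Called lists numbered 15, of which 5 pointed up and 10 down. Of all lists, 27 had 0 members past the authors' threshold, with 23 higher and 36 lower members at an unadjusted p of 0.05 among their 462.

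Genes were named by a rule fixed in advance: Gnaq, then the 12 largest changes in each direction and the 5 smallest p in each direction among called genes with a mean of at least 1 CPM, full separation of the genotypes and an established symbol, then up to 4 called members of each list in each direction, or the member with the smallest p where none was called. Because no value per library was used, 1 CPM was read from the summed average expression, where it equals about 27 units, and separation as the bound above. The rule named 73 called and 26 other genes besides Gnaq. Genes with near-identical copies, such as Hba-a1 and Hba-a2, Hspa1a and Hspa1b, the Serpinb3 genes, the stefin A genes and the Gsta genes, are uncertain, since the counting step could have split their reads.

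The steps were tested on simulated data for the same comparison, with 8 libraries of 20152 genes at the implied spread and 200 changed genes. The rebuilt p equalled that of a direct fit within rounding, and 0 of the 270 genes above the separation bound overlapped, while the bound found 34.8% of the separated genes. The normal reference called 85% of 100 genes changed by 1 on the log2 scale and 100% of 100 changed by 2. The rebuilt model called 36% and 77%, and the 2 called 6 and 9 unchanged genes. The normal reference was given the spread that generated the data, which a real test must estimate. Its shares therefore do not describe the authors' test. In 50 simulations camera called 100% of shifted lists and 0.364% of the others. Genes were drawn independently there, and all members of a shifted list moved equally. Members of real lists can vary together, so these shares are not the error rates of the list tests.

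Alternatives that could be run were a stricter adjusted p of 0.01, genes of at least 1 CPM with adjustment repeated over them, the rebuilt model with and without that filter, removal of the length and GC trend, centring of fold changes on the median gene, camera on ranks and other preset correlations. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.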

Results

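RNA was sequenced from back skin dissected from mouse embryos at E14.5. Libraries came from 4 embryo samples carrying GNAQ R183Q and 4 wild-type samples, described in the labels as biologically independent and sharing a single batch label. GNAQ encodes the alpha subunit of the heterotrimeric G protein Gq, which couples receptors to phospholipase C beta, and the R183Q change is known from capillary malformations and Sturge-Weber syndrome. The labels used here do not say in which cells of the embryo the changed protein was made. The values come from the authors' comparison of the genotypes, which lists 20152 genes with a mean expression, a log2 fold change of GNAQ R183Q over wild type, a p-value and mean z-scores per genotype. Mean expression summed to 2.68e+07 over all genes, of which mitochondrially encoded genes took 8.38% and globin genes 0.487%. No value per library was used here, so the depth of each library is unknown, and errors are the intervals implied by the authors' fold changes and p-values.

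The design asks how gene expression in embryonic back skin differs between the genotypes. Gnaq, the altered gene, stood at a mean expression of 2023 with a log2 fold change of 0.09 in the authors' deposited table, with an implied 95% interval from -0.16 to 0.34 and an authors' adjusted p of 0.804. This level counts Gnaq reads of either allele and does not tell the R183Q allele from the wild-type allele, so it does not check the labels.

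Skin of GNAQ R183Q embryos had lower expression of genes that keratinocytes switch on as they leave the basal layer and build the cornified envelope. Of the 28 measured genes of suprabasal differentiation, 22 fell and 0 rose, and the list had a median log2 fold change of -1.20, a 2.29-fold decrease. Loricrin (Lor), a main protein of the cornified envelope, fell to a log2 fold change of -3.70 in the authors' deposited table, with an implied 95% interval from -4.29 to -3.10 and an authors' adjusted p of 6.07e-30. The suprabasal keratins Krt77 and Krt10 fell, at log2 fold changes of -2.28 and -1.31 in the authors' deposited table, with authors' adjusted p of 1.93e-24 and 8.60e-12, and suprabasin (Sbsn) fell, at -1.76 with 1.63e-19. Krt10 and Krt77 are abundant in this tissue, with mean expression of 36990 and 19432 in the authors' deposited table. The count was 24 fallen genes adjusted over the list alone, and camera placed the list below other genes with an adjusted p of 6.00e-58.

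Across the whole table, 622 genes passed an authors' adjusted p of 0.05, of which 127 rose and 495 fell, so that 79.6% of the changed genes were lower in the mutant. Of these, 237 changed at least 2-fold, 40 upward and 197 downward. The median log2 fold change of all genes was 0.01, and the median over the fallen genes was -0.90 against 0.74 over the risen genes. For 369 of the 622 genes, or 59.3%, the mean z-score passed 0.810, above which all 4 libraries of one genotype must lie above all 4 of the other. The 622 genes were called from the same libraries, so their share past the bound is not separate evidence. Among all 20152 genes 2.58% passed that bound, which 0.542% would pass by chance with normal spread. Chance separates 4 against 4 libraries in 2.86% of splits, but the bound misses many genes that do separate, so the 2 shares are not comparable.

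**Figure D1:**
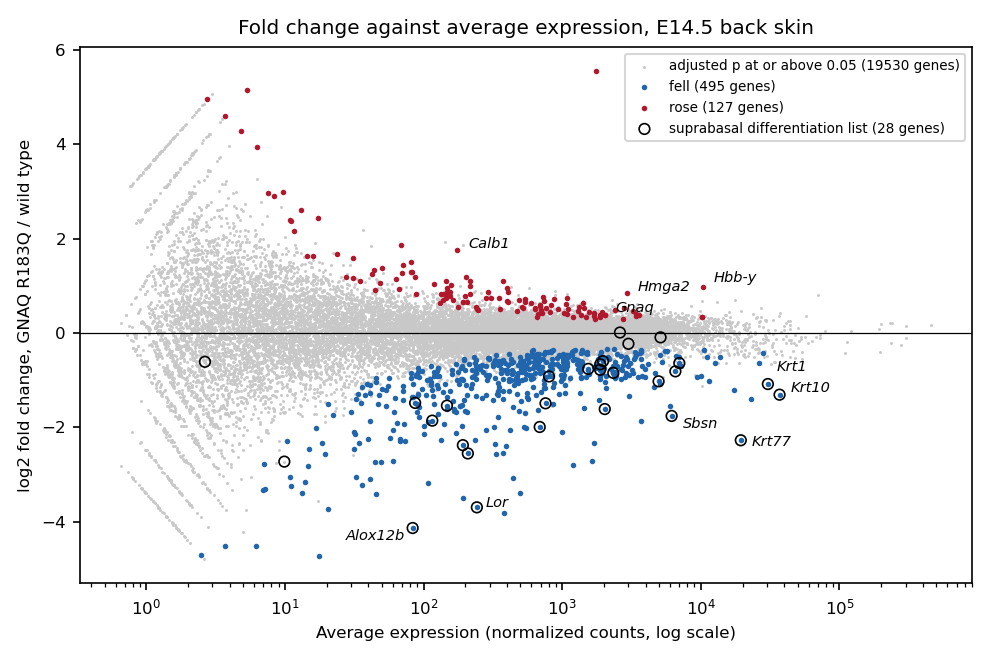
Log2 fold change of GNAQ R183Q over wild type (y axis) against average expression in normalized counts on a log scale (x axis) for 20152 genes from the authors' deposited table. Blue points are the 495 genes that fell and red points the 127 that rose at an authors' adjusted p of 0.05, grey points the other genes, and black circles the 28 measured genes of the suprabasal differentiation list, of which 22 fell.

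Genes of other epidermal layers were also examined. Of 14 measured periderm genes, which mark the outermost transient layer of the embryo, 4 fell and 0 rose, 9 fell adjusted over the list alone, the median was -0.77, and camera gave an adjusted p of 2.20e-08. Among them Ly6d and the galectin gene Lgals3 fell, at -1.64 and -1.58 in the authors' deposited table, and so did the keratins Krt4 at -1.20 and Krt13 at -2.06. Of 19 basal epidermis genes, 3 fell and 0 rose, also adjusted over the list alone, with a median of -0.12 and a camera adjusted p of 0.0842. The 3 were Krt15 at -1.01, Sfn at -0.91 and the desmosome-associated Perp at -0.64 in the authors' deposited table. At an unadjusted p of 0.05 the basal list held 6 lower genes and 1 higher gene. After removal of the length and GC trend 1 of its genes fell and 1 rose. The main basal keratins Krt5 and Krt14, singled out after their values were seen, had log2 fold changes of -0.12 and -0.19 in the authors' deposited table, and implied 95% intervals from -0.40 to 0.16 and from -0.56 to 0.18. Of 21 hair placode genes 0 passed, also adjusted over the list alone, and 2 were higher at an unadjusted p of 0.05, with a camera adjusted p of 0.489. Its smallest p belonged to the Wnt inhibitor Dkk4, with a log2 fold change of 0.47 and an authors' adjusted p of 0.136 in the authors' deposited table.

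The largest changes are given here for genes with a mean of at least 1 CPM, an established symbol and a mean z-score past the separation bound, so larger changes of other genes are left out. The epidermal lipoxygenase gene Alox12b had the lowest log2 fold change of the genes named by the selection rule, -4.14 in the authors' deposited table, with an implied 95% interval from -5.99 to -2.28. The ceramidase gene Acer1 fell, at -3.07, as did the phospholipase gene Pla2g4e at -2.35, the kallikrein protease gene Klk5 at -3.22 and the serpin gene Serpinb2 at -3.39 in the authors' deposited table. Lypd5 at -3.81, Wfdc5 at -3.41, Cyp2b19 at -3.18, Orm1 at -3.10, the complement gene C6 at -3.06, Calm4 at -2.79, the adaptor gene Blnk at -2.74 and Gprin2 at -2.56 completed the largest falls or those of smallest p within these limits in the authors' deposited table. Increases among genes within these limits were smaller. The calcium-binding protein gene Calb1 led with 1.76 and an implied 95% interval from 1.20 to 2.32 in the authors' deposited table, followed by Thsd7b at 1.51, Wnt9b at 1.34, Fam184b at 1.30, T2 at 1.26, the GABA-synthesis gene Gad2 at 1.19 and the netrin receptor gene Dcc at 1.10. Spock3 at 1.09, Cpa6 at 1.05, Slc24a2 at 1.01, the tight-junction gene Cldn6 at 1.00 and Slc16a9 at 0.96 completed the largest increases within these limits in the authors' deposited table. The smallest p-values among risers within these limits belonged to Rimklb, at 0.94 with an authors' adjusted p of 1.03e-09 in the authors' deposited table, and to Hmga2, a chromatin protein gene of embryonic growth, at 0.84 with 4.69e-08.

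**Figure D2:**
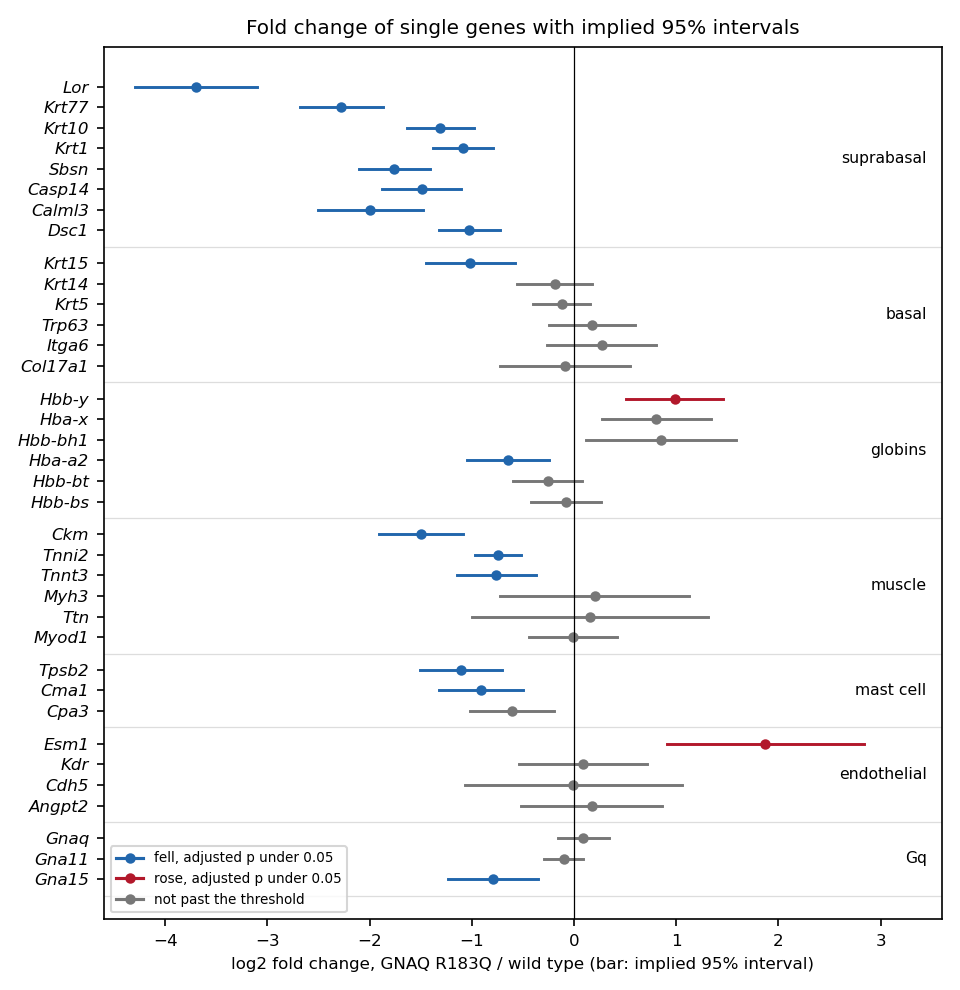
Log2 fold change of GNAQ R183Q over wild type (x axis) for single genes grouped by tissue or pathway (y axis), from the authors' deposited table, with bars for the implied 95% interval, blue for genes that fell, red for genes that rose and grey for genes that did not pass an authors' adjusted p of 0.05. The interval of Lor runs from -4.29 to -3.10 while that of Krt5 runs from -0.40 to 0.16, and genes beyond those of the selection rule were picked for the plot after their values were seen.

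Lists of muscle, adipogenic and fibroblast genes also included decreases, which RNA of dissected back skin cannot place in a layer. Of 28 skeletal muscle genes 6 fell and 0 rose, 9 fell adjusted over the list alone, the median was -0.21, and camera gave an adjusted p of 6.42e-06. That adjusted p was 0.0305 at a preset correlation of 0.1, 0.00648 after removal of the length and GC trend and 0.242 with both. Muscle creatine kinase (Ckm) fell, at -1.50, as did the fast troponin genes Tnni2 and Tnnt3 at -0.74 and -0.76 and the myogenic regulator Myf6 at -0.90 in the authors' deposited table. Of 11 adipogenic genes 2 fell and 0 rose, also adjusted over the list alone, namely the regulators Pparg at -0.74 and Cebpa at -0.66 in the authors' deposited table. The camera adjusted p of that list was 0.0340, and it was 0.201 at a preset correlation of 0.1. Of 24 dermal fibroblast genes 4 fell and 0 rose, also adjusted over the list alone, with a median of -0.08 and a camera adjusted p of 0.0816. They were Dpp4 at -0.64, Mfap5 at -1.21, the dermatopontin gene Dpt at -0.50 and Pi16 at -2.45 in the authors' deposited table. Pi16 had an average expression of 14.8, below the level read as 1 CPM, and was not shown to separate the genotypes. Among 31 genes of fibrillar matrix and crosslinking only the lysyl oxidase gene Loxl1 passed, at -0.84 in the authors' deposited table, also adjusted over the list alone (camera adjusted p 0.671). Of 23 matrix proteases and inhibitors Adamts20 rose, at 0.55, and Mmp23 fell, at -0.91 in the authors' deposited table, the same 1 and 1 adjusted over the list alone (camera adjusted p 0.317). In the dermal condensate list of 20 genes Inhba rose, at 0.59, and Cdkn1a fell, at -0.88 in the authors' deposited table, again 1 and 1 adjusted over the list alone (camera adjusted p 0.787). Of 14 cartilage and bone genes 0 passed over all genes, 2 fell adjusted over the list alone and 2 were lower at an unadjusted p of 0.05 (camera adjusted p 0.622). Cnmd had the smallest p, at -1.07 and an authors' adjusted p of 0.0857 in the authors' deposited table.

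Embryonic globin genes and definitive erythroid genes were listed separately. All 4 embryonic globin genes had positive fold changes, 1 rose over all genes and 3 adjusted over the list alone, the median was 0.92 and camera gave an adjusted p of 0.00235. The embryonic beta-like globin gene Hbb-y rose 1.98-fold in the authors' deposited table, with an implied 95% interval of the log2 fold change from 0.51 to 1.46 and an authors' adjusted p of 0.00329. Its mean z-score in the mutant group was 0.789, under the separation bound, so the genotypes were not shown to separate for Hbb-y. Of 20 definitive erythroid genes 2 fell and 0 rose, 3 fell adjusted over the list alone, and the median was -0.31 with a camera adjusted p of 0.00690. The 2 were Hemgn at -0.95 and the adult alpha globin gene Hba-a2 at -0.65 in the authors' deposited table, the latter uncertain because Hba-a1 is nearly identical. Hba-a2 passed narrowly, with an authors' adjusted p of 0.0492 in the authors' deposited table, and lost its call after centring, with an adjusted p of 0.0502, and after removal of the length and GC trend, with 0.386. The definitive erythroid call was lost at a preset correlation of 0.1, with an adjusted p of 0.201, and after removal of the transcript length and GC trend, with an adjusted p of 0.0506.

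Mast cell genes were lower. Of 11 measured members 3 fell and 0 rose, 5 fell adjusted over the list alone, all 11 fold changes were negative with a median of -0.65, and camera gave an adjusted p of 1.82e-06. The tryptase gene Tpsb2 fell, at -1.11, as did the chymase gene Cma1 at -0.91 and the granule proteoglycan gene Srgn at -0.56 in the authors' deposited table. Macrophage, neutrophil and lymphocyte, and platelet lists of 20, 14 and 15 measured genes had 0 members past the authors' DESeq2 threshold, also adjusted over the list alone. At an unadjusted p of 0.05 they held 2, 1 and 2 lower genes, and the platelet list 1 higher gene, with camera adjusted p of 0.578, 0.749 and 0.362. The smallest p-values belonged to Pf4 at -0.65 for macrophages, S100a9 at -0.68 for neutrophils and F2rl2 at 1.99 for platelets, with authors' adjusted p of 0.143, 0.263 and 0.101 in the authors' deposited table. F2rl2 had an average expression of 6.98, below the level read as 1 CPM.

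Endothelial identity genes showed no member past the threshold. The pan-endothelial, arterial, venous and lymphatic lists of 24, 18, 11 and 13 measured genes had medians of 0.00, 0.12, 0.04 and 0.01, and 0 members passed the authors' DESeq2 threshold, also adjusted over the list alone. At an unadjusted p of 0.05 there were 3 lower pan-endothelial genes and 0 genes in the other lists, and the camera adjusted p were 0.671, 0.322, 0.622 and 0.959. Their smallest p-values belonged to Sox18 at -0.54, Nrp1 at 0.43, Tll1 at 0.50 and Ccl21a at -0.34 in the authors' deposited table, with authors' adjusted p of 0.294, 0.353, 0.408 and 0.518. Of 18 angiogenic tip cell genes 1 rose and 0 fell, 4 rose adjusted over the list alone, and camera gave an adjusted p of 0.0154, which was 0.201 at a preset correlation of 0.1. The 1 was Esm1, a secreted marker of sprouting endothelium, which rose 3.65-fold in the authors' deposited table. The implied 95% interval of its log2 fold change ran from 0.90 to 2.83. Its mean z-score in the mutant group was 0.704, under the separation bound, so the genotypes were not shown to separate for Esm1. Of 26 hypoxia and glycolysis genes 23 had positive fold changes but 0 passed the authors' DESeq2 threshold, against 4 at an unadjusted p of 0.05 and 2 adjusted over the list alone. Camera gave that list an adjusted p of 0.00525, which was 0.201 at a preset correlation of 0.1, and its smallest p belonged to Pfkfb3 at 0.83 with an authors' adjusted p of 0.0720 in the authors' deposited table. Of 18 mural cell genes the potassium channel gene Kcnj8 fell, at -0.55 in the authors' deposited table, also adjusted over the list alone (camera adjusted p 0.981). Of 21 basement membrane genes 0 passed, also adjusted over the list alone, and 1 was higher at an unadjusted p of 0.05. It was Lama1 at 0.84 with an authors' adjusted p of 0.232 in the authors' deposited table (camera adjusted p 0.0788). The tip cell list shares Vegfa and Adm with the hypoxia list, and Col4a1, Col4a2, Nid2 and Lamb1 with the basement membrane list. The tests of these lists are therefore not independent.

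Signalling lists held few changed genes. Of 23 components of the Gq pathway 1 fell, also adjusted over the list alone, with a median of 0.08 and a camera adjusted p of 0.776. It was Gna15, another Gq-class alpha subunit, at -0.79 with an authors' adjusted p of 0.0198 in the authors' deposited table. It lost its call after removal of the length and GC trend, with an adjusted p of 0.182 from the normal reference. Another member of the Gq list, 1 gene, was called higher after that removal. The lists of MAPK feedback targets and calcineurin-NFAT targets, of 20 and 14 measured genes, had 0 members past the authors' DESeq2 threshold, also adjusted over the list alone, and 1 lower gene each at an unadjusted p of 0.05. Camera gave them adjusted p of 0.921 and 0.409, and their smallest p-values belonged to Il1rl1 at -0.51 and Orai1 at -0.47 in the authors' deposited table, with authors' adjusted p of 0.0968 and 0.155. Of 19 immediate early genes 3 fell and 0 rose, 6 fell adjusted over the list alone, and camera gave an adjusted p of 0.000968, which was 0.0807 at a preset correlation of 0.1. They were Klf4 at -0.78, which is also a member of the suprabasal list, the mRNA-decay factor gene Zfp36 at -0.78 and Junb at -1.24 in the authors' deposited table. Of 19 YAP-TAZ targets the coagulation initiator F3 fell 3.97-fold in the authors' deposited table, also adjusted over the list alone, while 15 members had positive fold changes (camera adjusted p 0.657). NF-kB and inflammatory targets, 18 genes, had 0 members past the authors' DESeq2 threshold, also adjusted over the list alone, and 2 higher genes at an unadjusted p of 0.05. Camera gave that list an adjusted p of 0.0463 toward higher expression, which was 0.344 at a preset correlation of 0.1, and its smallest p belonged to Vcam1 at 0.46 with an authors' adjusted p of 0.0785 in the authors' deposited table.

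Targets of interferon, Wnt, Hedgehog and Notch, in lists of 20, 18, 9 and 11 measured genes, had 0 members past the authors' DESeq2 threshold, also adjusted over the list alone. At an unadjusted p of 0.05 they held 1, 2, 0 and 1 lower genes and 0, 2, 1 and 0 higher genes, and camera gave adjusted p of 0.715, 0.495, 0.402 and 0.622. Their smallest p-values belonged to Ifih1 at -0.56, Dkk4 at 0.47, Sfrp1 at 0.39 and Nrarp at -0.41, with authors' adjusted p of 0.199, 0.136, 0.185 and 0.310 in the authors' deposited table. Of 15 BMP targets 0 passed over all genes, 1 rose and 3 fell adjusted over the list alone, and 1 was higher and 5 lower at an unadjusted p of 0.05. The smallest p belonged to Id1, at -0.85 with an authors' adjusted p of 0.0870 in the authors' deposited table (camera adjusted p 0.0816). Of 18 p53 targets 3 fell and 0 rose, also adjusted over the list alone, with a camera adjusted p of 0.00252, which was 0.114 at a preset correlation of 0.1. The 3 were the cell-cycle inhibitor Cdkn1a at -0.88, Sesn2 at -0.66 and the epidermal Perp at -0.64 in the authors' deposited table. Sesn2 was also the 1 of 17 unfolded protein response genes that fell, also adjusted over the list alone (camera adjusted p 0.548).

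Neural crest and nerve lists showed 1 changed gene. It was Mal, a myelin and epithelial membrane protein gene, which fell by 1.34 in the authors' deposited table as 1 of 18 Schwann and glial genes, also adjusted over the list alone (camera adjusted p 0.495). Of 16 melanocyte genes 0 passed over all genes, 1 rose and 1 fell adjusted over the list alone, and 1 was higher and 1 lower at an unadjusted p of 0.05. The smallest p was that of Rab38, at -0.53 with an authors' adjusted p of 0.0721 in the authors' deposited table (camera adjusted p 0.216). Of 16 neuronal genes 0 passed, also adjusted over the list alone, and Tubb3 was higher at an unadjusted p of 0.05, at 0.65 with an authors' adjusted p of 0.201 in the authors' deposited table (camera adjusted p 0.622).

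Mitotic genes were slightly higher as a group. Of 25 genes of G2 and M phase 24 had positive fold changes, 2 rose over all genes and 13 adjusted over the list alone, the median was 0.28, and camera gave an adjusted p of 3.18e-10. The spindle checkpoint kinase gene Bub1 rose by 0.39 and the mitotic kinesin gene Kif23 by 0.30 in the authors' deposited table. Of 25 S phase genes 0 passed the authors' DESeq2 threshold, 3 were higher at an unadjusted p of 0.05 and 1 adjusted over the list alone, namely Mcm6 at 0.26 with an authors' adjusted p of 0.0570 in the authors' deposited table (camera adjusted p 0.129). Cytosolic ribosomal protein genes had negative fold changes in 43 of 45 cases, with a median of -0.39 and a camera adjusted p of 4.86e-07. None of the 45 passed the authors' DESeq2 threshold, also adjusted over the list alone, 13 were lower at an unadjusted p of 0.05, and the smallest p belonged to Rplp0 at -0.54 with an authors' adjusted p of 0.147 in the authors' deposited table. Outside these 45, and chosen after its values were seen, the ribosomal protein gene Rpl36 fell, at -0.94 with an authors' adjusted p of 0.0443 in the authors' deposited table.

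Stress and position genes complete the lists. Of 14 heat shock genes 3 fell and 0 rose, also adjusted over the list alone, with a camera adjusted p of 0.0257, which was 0.201 at a preset correlation of 0.1. They were the near-identical Hspa1a and Hspa1b, at -1.65 and -1.44, whose reads may not be told apart, and Hspb1 at -0.92 in the authors' deposited table. Of 13 mitochondrially encoded genes 0 passed over all genes, 1 rose adjusted over the list alone and 2 were higher at an unadjusted p of 0.05, with mt-Atp8 at 0.70 and an authors' adjusted p of 0.0520 in the authors' deposited table (camera adjusted p 0.173). Of 19 Hox genes 0 passed, also adjusted over the list alone, with 2 higher and 1 lower at an unadjusted p of 0.05, and Hoxa9 at 0.44 had an authors' adjusted p of 0.149 in the authors' deposited table (camera adjusted p 0.0788). The Hox list was called toward higher expression after removal of the length and GC trend, with a camera adjusted p of 0.00295, and on ranks, with 0.0418. After removal of the trend the S phase and mitochondrially encoded lists were also called toward higher expression, each with a camera adjusted p of 0.0196. On ranks the BMP list was called toward lower and the basement membrane list toward higher expression, with camera adjusted p of 0.0418 and 0.0409. The 4 Y-linked genes, whose camera adjusted p was 0.817, and the 2 X-inactivation RNAs, too few for camera, had 0 members past the threshold, adjusted over the list alone or at an unadjusted p of 0.05. Uty stood at -0.80 with an authors' adjusted p of 0.932 and Tsix at 0.64 with 0.844 in the authors' deposited table.

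**Figure D3:**
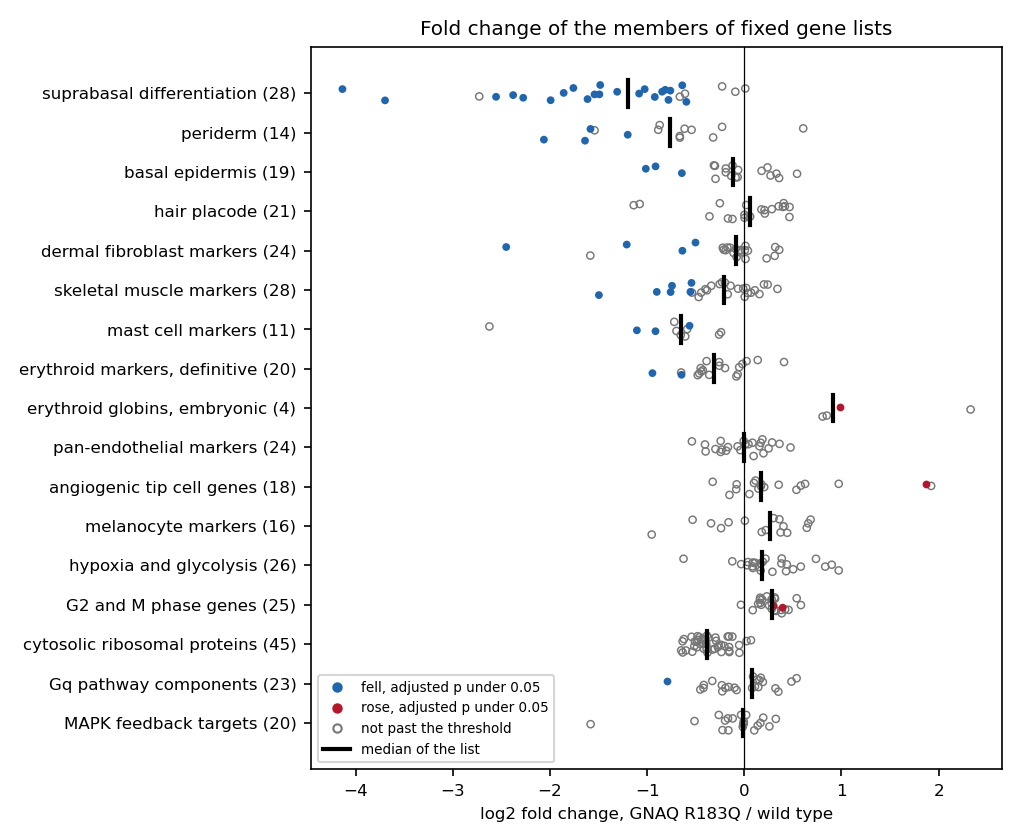
Log2 fold change of GNAQ R183Q over wild type (x axis) for each measured member of 17 of the fixed gene lists (y axis, number of members in brackets), from the authors' deposited table. Filled blue and red points fell and rose at an authors' adjusted p of 0.05, open points did not pass, and black bars mark the list medians, which run from -1.20 for suprabasal differentiation to 0.92 for embryonic globins.

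Fold changes also followed transcript properties. Across 13955 genes, which are not independent replicates, the log2 fold change had a Spearman rho of 0.365 with transcript length and -0.279 with GC content, and both together held 11.8% of its variance. The tenth of genes with the shortest transcripts had a median log2 fold change of -0.23 and the tenth with the longest 0.16. After removal of this trend 20 of the 22 suprabasal genes still fell, with a median of -1.13, as did 4 of 4 periderm, 3 of 3 mast cell, 3 of 6 muscle, 3 of 4 fibroblast, 1 of 2 adipogenic, 1 of 3 basal, 2 of 3 immediate early, 2 of 3 heat shock and 1 of 3 p53 genes. Adamts20, Mmp23, Loxl1 and Kif23 lost their call, with adjusted p of 0.0742, 0.112, 0.0775 and 0.0941. Their log2 fold changes went from 0.55, -0.91, -0.84 and 0.30 in the authors' deposited table to 0.43, -0.65, -0.69 and 0.27, and those of Gna15 and Hba-a2 from -0.79 and -0.65 to -0.57 and -0.39. The implied errors of these genes were left as they were, so the calls ended because the fold changes shrank, by less than 1 implied error for Kif23, Loxl1 and Adamts20. Of the named genes that had not passed, Il1rl1, Dkk4, Tubb3 and mt-Atp8 passed after removal of the trend, with adjusted p of 0.0203, 0.0125, 0.0388 and 0.0284. The median of the ribosomal protein genes went from -0.39 to -0.20, and the camera adjusted p of the heat shock list from 0.0257 to 0.0725.

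The authors' adjusted p-values (DESeq2, per the submitters' processing notes) are the test of single genes, and camera in limma, with adjustment over 48 lists, is the test of lists. A linear model of log2 CPM rebuilt from the mean z-scores, which borrows no spread between genes, called 0 of the 20152 genes after adjustment, with 2481 genes, including 619 of the 622, at an unadjusted p of 0.05. Among genes with a mean of at least 1 CPM the rebuilt model called 28.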

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

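Of the alternatives used here, the stricter adjusted p of 0.01 and the filter at 1 CPM were planned, and the rebuilt log2 CPM model, removal of the length and GC trend, centring, ranks and other preset correlations were chosen after seeing the data. No paired analysis was possible because the table holds genotype means, which carry no replicate numbers. For the same reason edgeR, DESeq2 and limma-voom fits, other scalings, the filter of at least 1 count, other pseudocounts, fits without each library, sex or muscle covariates, removal of globins, estimated correlations, fry and other splits of the libraries were not run. The count of 622 changed genes fell to 386 at an adjusted p of 0.01, since fewer genes pass a stricter threshold. It was 670 among genes of at least 1 CPM (586 shared), 615 after centring (613 shared) and 578 after removal of the trend, with 421 shared and 70.2% of them lower against 79.6%. The rebuilt model in Python called 0 genes, and 0 changed at least 2-fold, with a smallest adjusted p of 0.0503 and 2481 genes at an unadjusted p of 0.05. At an adjusted p of 0.1 it called 141 genes, 119 of them among the 622. With at least 1 CPM it called 28 genes, 26 of them shared, and 13 that changed at least 2-fold against 237. Its statistics had a Spearman rho of 0.984 with the authors' across genes, and it shares no spread between genes. The 15 called lists became 9 at a preset correlation of 0.05 and 7 at 0.1, where a larger error is assumed. At 0.1 with the trend also removed 5 were left, namely suprabasal, periderm, mast cell, G2 and M and embryonic globin lists, and the trend accounts for the further loss of muscle and ribosomal lists. Removing the trend alone called 16, losing definitive erythroid and heat shock and gaining S phase, mitochondrially encoded and Hox lists. Ranks called 17, losing heat shock and gaining BMP, basement membrane and Hox lists. The rebuilt statistics called 12, losing NF-kB, hypoxia, tip cell and heat shock and gaining S phase lists. The filter at 1 CPM called 11 of 47, losing NF-kB, adipogenic and heat shock lists, with too few embryonic globins to test. A list threshold of 0.01 left 11, and centring 15. Of the 603 called genes with a transcript length 0 changed direction after removal of the trend, and no called list turned. Of the 73 named called genes, 61 passed at 0.01, 72 passed the filter at 1 CPM, 72 passed after centring, 59 passed after removal of the trend, and 0 passed in the rebuilt model against 9 with its filter. Gnaq stayed past no threshold in each alternative run on it.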

Other observations

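The gene lists, gene families and neighbour counts of this part, and the tests of keratinocyte loss, embryo sex and blood content, were chosen after seeing the data, while the tests of length, of scale and of stage were set before the values they measure were seen. A list of skin barrier lipid genes was made after some of its members had been seen to fall, so only the members not seen before test it. Among these 17 genes 5 fell and 0 rose, with a median log2 fold change of -0.36 and a camera p of 2.45e-11 (adjusted over 4 such lists, 9.79e-11). The 5 were the very-long-chain elongases Elovl1 and Elovl4, at -0.97 and -1.14, the omega-hydroxylase Cyp4f39 at -1.17, the acylceramide synthase Pnpla1 at -1.08 and the cholesterol sulfotransferase Sult2b1 at -1.69 in the authors' deposited table. Of desmosome and cornified cell junction genes, the 14 members not seen before gave a camera p of 0.700 (adjusted, 0.700), with 1 fallen gene, Gjb5 at -2.25 in the authors' deposited table. For 32 unseen ciliary transport genes the median was 0.09 with a camera p of 0.0202 (adjusted, 0.0403). That p was 0.0957 at a preset correlation of 0.05. Of these 32 genes 0 passed over all genes, but the 4 members set aside as seen, Rpgrip1l, Wdr35, Ift88 and Dzip1l, had all risen. The members set aside in the barrier lipid and junction lists had also all passed the threshold. Unseen members of these lists are thus a remainder with fewer called genes, which biases their tests toward no change.

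Fallen genes lay beside each other in the genomic order of tested genes. Genes that were not tested were left out of this order, so neighbours and spans count tested genes only. In the GRCm38.p6 order 48 pairs of neighbouring tested genes both fell, against a mean of 12.4 and a highest value of 27 in 10000 permutations (permutation p 0.0001, the smallest they can give). For the 118 placed risers there were 0 pairs against a permuted mean of 0.709, too few to compare the directions. Of 8 groups of at least 4 fallen genes, 6 held related genes, namely 7 of 9 consecutive genes of the Serpinb cluster on chromosome 1, Krt1, Krt77, Krt4 and Krt78 within 6 genes on chromosome 15, Csta1, Cstdc5, Stfa2 and Stfa3 within 7 on chromosome 16, Sprr1b, Sprr3, Sprr1a and Ivl as 4 of 4 on chromosome 3, Gsta4, Gsta1, Gm3776 and Gsta2 within 5 on chromosome 9, and Klk11, Klk8, Klk7 and Klk5 within 6 on chromosome 7. The other 2 were Elovl1, 2610528J11Rik, Gm52677 and Cfap57 within 8 on chromosome 4, and Gm12764, Kctd15, Pepd and Cebpa within 10 on chromosome 7. Of 600 tests of symbol families by direction, Fisher's exact test with Benjamini-Hochberg adjustment called 4. They were Serpinb with 7 of 18 fallen (adjusted p 7.81e-05), Krt with 8 of 43 (adjusted p 0.00256), Klk with 4 of 9 (adjusted p 0.00822) and genes starting with Il and a number with 8 of 65 (adjusted p 0.0278), among them Il1rn, Il20rb and Il22ra1. Neighbours are often paralogs whose reads can be shared, and genes are not independent replicates.

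The riser with the highest fold change, Rpl34-ps1, stood at 5.55 with an implied 95% interval from 3.26 to 7.84 and an average expression of 1745 in the authors' deposited table. Its mean z-score was 0.720 and its median z-scores were 1.14 and -0.81, so the genotypes were not shown to separate, and as a pseudogene it shares sequence with Rpl34.

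For the fall of suprabasal differentiation genes, a loss of keratinocytes of all layers would lower basal genes alike. The basal epidermis list had a median of -0.12 with an upper quartile of 0.21, against -1.20 for the suprabasal list. Of its 19 members 13 had negative fold changes, and it does not measure the number of suprabasal cells. Removing the length and GC trend left 20 of the 22 fallen genes past the threshold with a median of -1.13, so that trend is not the whole cause. Sex would separate the genotypes by Y-linked genes, whose largest absolute mean z-score was 0.211, while 16 of the 22 fallen genes passed the separation bound. The z-scores of Y-linked genes were best matched by 1 high library of 4 in the mutants and 2 of 4 in wild type, an imbalance that cannot separate the genotypes but may add to the fold changes. Fewer suprabasal cells, an effect of the genotype and a delay of the mutant embryos, which may act on the same genes, stay open. So do litter and differences between libraries that genotype means cannot show.

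Lower ribosomal protein expression was weighed against the length and GC trend and against a shift of the whole scale. Genes of similar expression that encode no ribosomal protein had a median of 0.0143 (137 genes), which argues against a shift of the scale. Removing the length and GC trend took the list median from -0.39 to -0.20, with a camera adjusted p of 0.0131 at the preset correlation and 0.333 at 0.1. Other short transcripts, 1324 genes, had a median of -0.22, so a trend tied to RNA or library quality cannot be told apart from a change of these genes, because nearly all of them are short.

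For higher embryonic globins beside lower definitive erythroid genes, the test of blood content was the median of the definitive erythroid list, -0.31. That median is itself part of the pattern and was seen before the test was set. More blood of unchanged makeup would still raise definitive genes, yet 17 of 20 had negative fold changes, with quartiles of -0.45 and -0.06. These values argue against more blood as the sole cause for the 20 genes, while other differences in blood stay open. An earlier developmental stage of the mutant embryos may account for this pattern, and the rise of Hmga2 prompted a test on 10 oncofetal genes not seen before, of which 8 had positive fold changes with a median of 0.08 and a camera p of 0.0986 (adjusted, 0.131). That p was 0.0319 with the rebuilt statistics and 0.152 and 0.211 at preset correlations of 0.05 and 0.1. After removal of the length and GC trend it was 0.379. Hmga2, Igf2bp1 and Dlk1 were set aside as seen, of which Hmga2 and Igf2bp1 had risen, at 0.84 and 0.38 in the authors' deposited table. The 10 genes left are thus a remainder without called genes, which biases the test toward no change. All 13 members gave a camera p of 0.00212, but they include the gene that prompted the test. The test left stage open, as a candidate explanation that cannot be told apart from an effect of the genotype without staged embryos. The embryonic globin call rests on 4 genes, of which Hbb-y alone rose over all genes.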
